A study of Mus musculus with 18 samples.

How the data were processed

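Whole bone marrow RNA of female C3H mice was hybridised to one-colour Agilent 4x44K mouse arrays, 1 Cy3-labelled sample per array. The design holds 2 ages (1 and 8 weeks) and 3 conditions (unirradiated, 6 h and 24 h after 2 Gy of gamma rays), with 3 arrays in each of the 6 groups. Groups were taken from the labels, with 1 mouse per array per the labels.

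The deposited array files hold intensity values per spot, background-subtracted and spatially detrended by Agilent Feature Extraction but not scaled between arrays. Version 11.5.1 is named per the labels, while the file headers name an older release. The deposited series matrix holds log2 values made by the authors by shifting each array by its 75th percentile and subtracting each probe's median over the 18 arrays. That description was checked by recomputing those values from the array files for 41174 matched probes of 41252, with r of 1 and slopes of 0.999 to 1.00 on every array. Further flags per spot (well above background, saturated, non-uniform, population outlier) are 0 or 1 in the deposited array files. Reported values start from the array files, since probe-centred values hold no signal level.

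Control spots were left out, and 43379 spots per array gave 41174 probes. Spots with a non-uniformity or population outlier flag (77 to 123 per array) were set aside, and log2 signal was averaged over the remaining spots of a probe. A probe counted as well above background on an array where at least 0.5 of its spots did. The array's 75th percentile over all non-control probes (raw signal 480.0 to 755.8) was subtracted, so a value of 0 lies at that percentile. Gene symbols came from the platform annotation in the array files, where 24844 probes carry a symbol and 16330 do not. Of 17178 genes, 5955 have more than 1 probe, and the probe with the highest mean signal was used. Genes were tested when well above background on all 3 arrays of at least 1 group, which left out 5284 dim genes and 10 genes with an outlier spot on some array. Saturated spots numbered 0 to 2 per array.

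Differences were tested with limma 3.58.1 in R 4.3.3 (files read with version 1.17.8 of data.table), with 1 mean per group, empirical Bayes variances with an intensity trend and all 18 arrays in the fit (12 residual and 4.33 prior degrees of freedom). There were 9 comparisons. These were 6 h and 24 h against control at each age, 8 weeks against 1 week in controls, the difference of the 6 h and of the 24 h response between ages, and 24 h against 6 h at each age. P-values were two-sided, adjusted by Benjamini and Hochberg within a comparison, and called under 0.05. Gene lists were compared with all other tested genes by camera with a preset correlation of 0.01, adjusted over 32 lists. The correlation between members was also estimated, which lowers the number of lists past the threshold from 8, 14, 18, 20, 22, 16, 15, 9 and 13 to 1, 2, 1, 2, 0, 0, 0, 2 and 1 in the order of comparisons above.

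The lists cover chemokine ligands and receptors, p53 targets, apoptosis machinery, DNA replication, mitosis, DNA repair, interferon-stimulated genes, inflammatory cytokines, NF-kB targets, niche factors, and immediate early and heat shock genes. For cell types they cover stem and progenitor cells, erythroid cells, B-cell precursors, mature B cells, T cells, NK cells, early granulocytes, late neutrophils, monocytes, resident macrophages, mast cells with basophils and eosinophils, and megakaryocytes. For tissues they cover stromal fibroblasts, osteoblasts, osteoclasts, cartilage, endothelium, adipocytes, skeletal muscle, and fetal and neonatal growth genes. The lists, tests, thresholds, gene-naming rule and the alternatives listed last, apart from those marked, were fixed before the data were examined.

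Genes named in the text follow a rule. In each of the 5 comparisons with controls it takes the 10 largest rises and 10 largest falls with adjusted p under 0.05, no overlap between the groups' arrays and signal well above background on all 3 arrays of the higher group. In the other 4 comparisons it takes the 6 highest and 6 lowest differences with adjusted p under 0.05. From each list it takes up to 4 members with the smallest adjusted p, of which some are named. Every chemokine ligand called in any irradiation comparison is named, and always Cdkn1a, Mdm2, Ccnb1, Mpo, Cd79a, Cd3e, Ccl2 and Cxcl12. Hbb-b1 and Kit were also to be named always but have no probe with that symbol here. Names that are clone or locus identifiers and immunoglobulin or T-cell receptor segments were left out. Genes named outside the rule are marked as chosen after their values were seen.

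Whether replicate numbers pair the arrays across groups was checked on residuals. Among 45 pairs with the same number r ran from -0.27 to 0.32 (median -0.015), 9 exceeded 0.1, and 9 of 18 arrays correlated best with an array of their own number, so no pairing was used. Arrays lie on 5 slides scanned on 1 day, and slide was tried as a block. Tests on simulated data with 200 changed genes, far fewer than called here, may not carry over. Of 50 genes each at 1.5, 2, 3 and 4-fold, 72, 90, 98 and 94% were recovered at 8 weeks 24 h. The 24 h age difference gave 56, 80, 96 and 94%. Unchanged genes made up 5.7% and 7.6% of calls, and a comparison left unchanged gave 0. Correlations between probes used 100000 permutations of arrays (seed 1).

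Alternatives were normexp background correction (offset 50), quantile scaling, the 75th percentile over probes well above background on all arrays, no background filter, genes well above background on all 18 arrays, outlier spots kept and the mean of a gene's probes. Further alternatives were a replicate block, a slide block, only the groups of the comparison, no variance trend, array weights, the authors' series matrix values, adjusted p under 0.01, a 2-fold minimum, fry, and leaving out each array. The plan named the mean spot signal for normexp, and the median spot signal took its place because the array files hold no mean signal column. A version of normexp with backgrounds above 10 times the array median reset to that median was added after seeing the data. Genomic sequence was not used here, and probes without a symbol were tested apart from the genes.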

Results

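Whole bone marrow of female C3H mice aged 1 or 8 weeks was measured on 18 arrays, unirradiated or 6 h or 24 h after 2 Gy of gamma rays. Each of the 6 groups holds 3 arrays. Between 21020 and 25566 of 41174 probes (51.05 to 62.09%) were well above background on each array. Of 17178 genes with a probe, 11884 were well above background on all 3 arrays of at least 1 group and were tested. Another 5284 genes were too dim, among them Cxcl1, Cxcl2, Cxcl5, Cxcl13, Il6 and Csf3. Replicates of a group correlated at r = 0.992 to 0.997, apart from 1-week control replicate 2 with r = 0.978 and 0.98 to the other 1-week controls. That array carries more skeletal muscle (list mean 6.39 log2 above the other 1-week controls) and cartilage transcript (5.60 above).

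**Figure D1:**
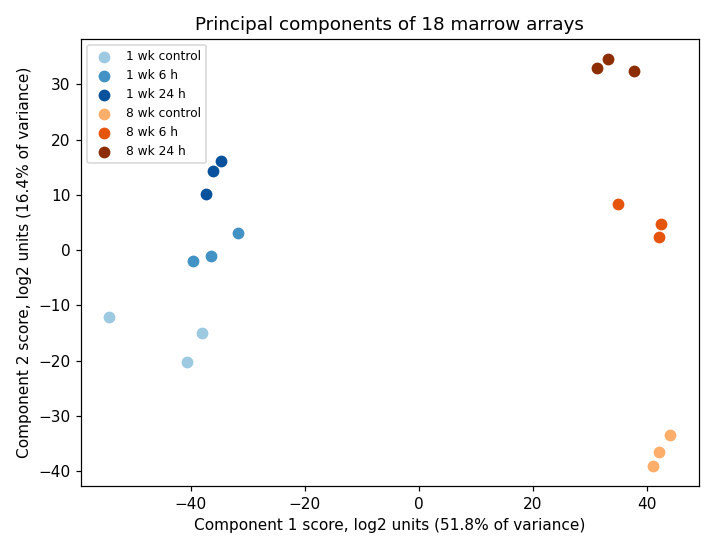
Scores of 18 arrays on the leading components of log2 signal, in log2 units, coloured by group, 1 point per array. The horizontal component (51.8% of variance) separates the ages and the vertical component (16.4%) orders control, 6 h and 24 h at each age.

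Numbers after gene names are log2 differences between group means ± standard error from the limma fit, with 3 arrays per group, and p-values are adjusted over the 11884 genes. For the largest changes named in the 5 comparisons with controls, no array of either group overlaps the other group. Where the lower group was well above background on no array, a bound is given as "at least N-fold". It takes the higher group's mean over the lower group's arrays, each raised to its weakest well-above-background signal, and ignores spread. Gene lists carry the mean log2 difference of their measured members, camera's adjusted p over 32 lists, and the adjusted p with an estimated correlation between members.

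Which genes changed 6 h after irradiation at 1 week? Of 11884 genes, 3031 rose and 3130 fell, and 392 of these 6161 changed at least 2-fold. With slide as a block 5762 changed. On the slide with both groups the differences correlate at r = 0.844 with those from all arrays, which include its own and so raise every such r. Without 1-week control replicate 2 the count is 5683. The 6 h and 24 h comparisons at an age share 3 control arrays, so they are not independent.

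Among the 10 rises named here were Tgm5 (4.01 ± 0.43), Pdpk1 (3.97 ± 0.43), Ddx25 (3.97 ± 0.50), Trim55 (3.83 ± 0.43), Myo1e (3.58 ± 0.49), Lifr (3.51 ± 0.39) and Plcd3 (3.46 ± 0.33). The probes used for these 7 genes rose and fell together within groups. Only Pdpk1, Lifr and Myo1e have further measured probes, and these 5 lay between -0.11 and 0.27, while a dimmer probe of Myo1e was at 1.28. Deviations of Ddx25 from its group means followed those of Pdpk1 at r = 0.963 over 18 arrays (rho 0.901, permutation p = 3e-05, adjusted p = 0.000135, r = 0.915 without the 2 farthest arrays). For Plcd3, the weakest of the group, r was 0.836 (rho 0.662, permutation p = 0.00326, adjusted p = 0.00543, r = 0.651 without the 2 farthest arrays). Aqp5 rose at least 12.7-fold, Cpt1c by 3.73 ± 0.37 and Zmat3, a p53 target, by 3.42 ± 0.07. The correlation of 0.8 that defines the 7 genes was chosen after the correlations were seen. A transcript with a clone name, 1700007K13Rik, rose at least 11.2-fold and was chosen after its values were seen.

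**Figure D2:**
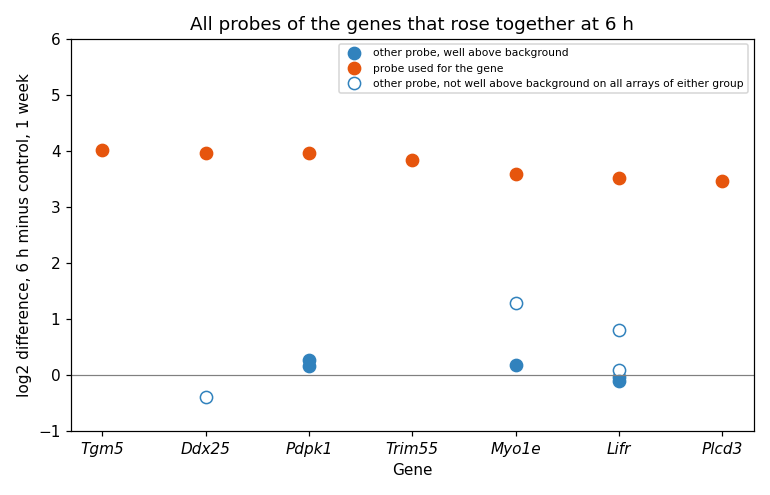
Log2 difference (6 h minus control, 1 week) of every probe of the 7 genes whose used probes rose together, 1 point per probe, 3 arrays per group. Used probes lie between 3.46 and 4.01, and the 5 other probes well above background lie between -0.11 and 0.27.

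Named falls at 6 h were Myom2 (-3.22 ± 0.98), Apobec2 (-3.08 ± 1.03), Thrb (-2.38 ± 0.16), Grb7 (-2.35 ± 0.59), Fgf13 (-2.25 ± 0.51), Smtnl2 (-2.14 ± 0.22), Rgma (-2.12 ± 0.67) and Gbp8 (-2.02 ± 0.12). Speer3 fell at least 5.59-fold and Olfr138 at least 2.23-fold. Myom2 and Apobec2 are muscle transcripts, and without 1-week control replicate 2 their differences are -1.65 (adjusted p = 0.0562) and -1.25 (adjusted p = 0.0756). Rgma is -0.87 (adjusted p = 0.0292) without that array and no longer past the threshold with slide as a block (-1.90, adjusted p = 0.0764).

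The p53 target genes rose in 28 of 31 measured members and 1 fell (mean 1.45, camera adjusted p = 1.59e-19, and 0.000469 with an estimated correlation). Phlda3 (3.26 ± 0.07), Ccng1 (3.27 ± 0.08) and Bbc3 (2.31 ± 0.08) were among them, and Cdkn1a rose by 2.33 ± 0.16 and Mdm2 by 0.96 ± 0.09. B-cell precursor genes fell in 15 of 16 members (mean -1.29, camera adjusted p = 5.25e-11, 0.271 with an estimated correlation), among them Dntt (-2.0 ± 0.10), Rag1 (-1.84 ± 0.10) and Blnk (-1.32 ± 0.07). Mpo fell by 0.33 ± 0.07, and Cd79a (-0.56 ± 0.29, adjusted p = 0.122) and Cd3e (-0.11 ± 0.36, adjusted p = 0.824) did not pass. Late neutrophil genes rose in 27 of 27 members (mean 0.66, camera adjusted p = 1.06e-11, 0.557 with an estimated correlation), with Chil3 at 1.18 ± 0.08 and Ngp at 0.70 ± 0.07. Erythroid genes rose in 23 of 26 members, 24 adjusted over the list alone (mean 0.58, camera adjusted p = 2.43e-09, 0.597 with an estimated correlation), including Alas2 (0.92 ± 0.08) and Trim10 (0.86 ± 0.06). Mitosis genes rose in 27 of 33 members, 29 adjusted over the list alone (mean 0.39, camera adjusted p = 5.25e-07, 0.597 with an estimated correlation). Ube2c rose by 1.23 ± 0.09 and Ckap2 by 0.66 ± 0.08, while the 0.24 ± 0.09 of Ccnb1 (adjusted p = 0.029) loses its call when any of several arrays is left out.

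Resident macrophage genes fell in 12 of 17 members and 1 rose (mean -0.70, camera adjusted p = 0.00022, 0.597 with an estimated correlation). The complement genes C1qa (-1.64 ± 0.14), C1qb (-1.27 ± 0.12) and C1qc (-1.59 ± 0.13) and the ficolin Fcna (-1.42 ± 0.11) fell. Mast cell, basophil and eosinophil genes rose in 9 of 15 members and 3 fell (mean 0.35, camera adjusted p = 0.014, 0.634 with an estimated correlation), with the eosinophil genes Ear1 (0.98 ± 0.08) and Prg2 (0.77 ± 0.08) rising. Chemokine receptors rose in 9 of 18 members and 2 fell, 11 and 2 adjusted over the list alone (mean 0.47, camera adjusted p = 0.0231, 0.597 with an estimated correlation), among them Ccr3 (1.00 ± 0.12) and Ccrl2 (0.97 ± 0.10). Skeletal muscle genes averaged -2.06 and cartilage genes -1.54 with 0 members past the threshold, following the 1-week control array rich in these tissues. The immediate early list averaged 0.22 (adjusted p = 0.0592), with Atf3 at 1.41 ± 0.13 and Myc at -1.09 ± 0.15. The number of arrays limits the precision, and differences in cell mixture are not separated from regulation within cells.

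What had changed by 24 h at 1 week? The threshold was passed by 4279 genes, of which 2192 rose, 2087 fell and 390 moved at least 2-fold. The count was 4280 with slide as a block, and the 2 shared slides gave r = 0.76 and 0.845. Named rises were Zmat3 (3.11 ± 0.07), the pentraxin Ptx3 (3.02 ± 0.31), Phlda3 (2.61 ± 0.07), Bmp4 (2.31 ± 0.14), Cdkn1a (2.29 ± 0.16), Ccng1 (2.28 ± 0.08), Fst (2.21 ± 0.26), Inka2 (2.20 ± 0.20) and Dglucy (2.13 ± 0.07). Plin1, an adipocyte gene, rose at least 2.16-fold. Among the falls were Grb7 (-3.51 ± 0.59), Dntt (-3.21 ± 0.10), Smtnl2 (-3.20 ± 0.22), Rag1 (-3.0 ± 0.10), Gfra1 (-2.88 ± 0.37), Myom2 (-2.74 ± 0.98), Thrb (-2.67 ± 0.16) and Arpp21 (-2.65 ± 0.15). Speer3 fell at least 5.73-fold and Sertad4 at least 5.15-fold. Myom2 is -1.17 (adjusted p = 0.202) without 1-week control replicate 2.

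B-cell precursor genes fell in 15 of 16 members (mean -1.75, camera adjusted p = 7.7e-19, and 0.0476 with an estimated correlation), Blnk at -1.59 ± 0.07 and Lef1 at -2.60 ± 0.13. Of the p53 target genes 27 of 31 rose and 0 fell (mean 0.94, camera adjusted p = 5.79e-18, and 0.000803 with an estimated correlation), with Psrc1 at 1.34 ± 0.08 and Mdm2 at 0.63 ± 0.09. All 27 late neutrophil genes rose (mean 0.74, camera adjusted p = 1.65e-18, 0.167 with an estimated correlation), among them the integrin Itgam (0.92 ± 0.08) and lactoferrin Ltf (0.92 ± 0.09). Resident macrophage genes now rose in 14 of 17 members (mean 0.65, camera adjusted p = 3.87e-08, 0.167 with an estimated correlation), with haem oxygenase Hmox1 at 1.78 ± 0.09, Spic at 0.95 ± 0.08 and Marco at 1.24 ± 0.14. Haematopoietic niche factors rose in 8 of 12 members, 9 adjusted over the list alone (mean 0.67, camera adjusted p = 0.000255, 0.167 with an estimated correlation), Igf1 by 0.98 ± 0.09 and Vcam1 by 0.73 ± 0.11. Mast cell, basophil and eosinophil genes rose in 8 of 15 members and 1 fell (mean 0.40, camera adjusted p = 0.00175, 0.397 with an estimated correlation), Epx by 0.91 ± 0.11. Erythroid genes rose in 11 of 26 members and 1 fell (mean 0.25, camera adjusted p = 0.00343, 0.687 with an estimated correlation), Bpgm by 1.15 ± 0.10 and Car1 by 0.82 ± 0.11.

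Stem and progenitor genes fell in 7 of 15 members (mean -0.40, camera adjusted p = 0.00458, 0.167 with an estimated correlation), among them Sox4 (-1.38 ± 0.08), Myb (-0.84 ± 0.06) and Cd34 (-0.54 ± 0.08). NK-cell genes fell in 5 of 13 members (mean -0.42, camera adjusted p = 0.0105, 0.577 with an estimated correlation), Gzma at -1.28 ± 0.13 and Nkg7 at -0.51 ± 0.08. DNA repair genes fell in 7 of 25 members and 1 rose (mean -0.20, camera adjusted p = 0.0105, 0.687 with an estimated correlation), Lig4 at -0.96 ± 0.08 and Parp1 at -0.74 ± 0.10. DNA replication genes fell in 7 of 33 members and 1 rose, 3 and 0 adjusted over the list alone (mean -0.11, camera adjusted p = 0.0472, 0.8 with an estimated correlation). Monocyte genes rose in 7 of 12 members and 1 fell (mean 0.25, camera adjusted p = 0.0435, 0.673 with an estimated correlation), Ms4a7 by 0.86 ± 0.11. Chemokine receptors rose in 7 of 18 members and 1 fell (mean 0.40, camera adjusted p = 0.0309, 0.525 with an estimated correlation), Ccr6 by 1.25 ± 0.15, while Ccr7 fell by 0.80 ± 0.13. The replication, monocyte and receptor lists each lose the call when certain arrays are left out. Mpo fell by 0.35 ± 0.07, and Cd3e (0.63 ± 0.36, adjusted p = 0.185) and Ccnb1 (-0.07 ± 0.09, adjusted p = 0.594) did not pass.

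Which genes changed 6 h after irradiation at 8 weeks? Here 2843 genes rose and 2626 fell, 474 of them at least 2-fold, and 5231 changed with slide as a block. The shared slide gave r = 0.9. Rises at 6 h included Gdf15 (4.71 ± 0.39), Phlda3 (3.90 ± 0.07), Ccn2 (3.73 ± 0.33), Zmat3 (3.56 ± 0.07), Hebp2 (3.42 ± 0.12), Ccng1 (3.18 ± 0.08) and Dnah2 (3.11 ± 0.14). A further probe of Dnah2 gave -0.45. Inka2 rose at least 12.6-fold, Cpt1c at least 10.3-fold and Tnfsf4 at least 3.63-fold, and 1700007K13Rik, chosen after its values were seen, at least 17-fold. Falls included Grb7 (-3.43 ± 0.59), Rag1 (-3.0 ± 0.10), Smtnl2 (-2.91 ± 0.22), Gfra1 (-2.28 ± 0.37) and Ebf1 (-2.21 ± 0.14). Bounded falls were Ren1 (at least 2.36-fold), Il33 (at least 2.11-fold), Gpam (at least 1.9-fold), Dnase1 (at least 1.42-fold) and Kcnj16 (at least 1.31-fold, and -0.33 with adjusted p = 0.596 when its probes are averaged).

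The p53 target genes rose in 27 of 31 members and 1 fell, 29 and 1 adjusted over the list alone (mean 1.47, camera adjusted p = 1e-21, and 0.000275 with an estimated correlation), Dcxr by 2.38 ± 0.08, Cdkn1a by 2.97 ± 0.16 and Mdm2 by 0.83 ± 0.09. B-cell precursor genes fell in 16 of 16 members (mean -1.53, camera adjusted p = 5.54e-16, 0.0869 with an estimated correlation), including the surrogate light chain genes Vpreb2 (-2.20 ± 0.13) and Vpreb3 (-1.54 ± 0.08), and Cd79a fell by 1.00 ± 0.29. Mature B-cell genes fell in 8 of 17 members and 1 rose (mean -0.28, camera adjusted p = 0.0451, 0.675 with an estimated correlation), with Blk at -1.06 ± 0.17 and Fcer2a rising by 1.28 ± 0.16, and the list call is lost under several settings. Late neutrophil genes rose in 24 of 27 members, 27 adjusted over the list alone (mean 0.58, camera adjusted p = 1.23e-11, 0.193 with an estimated correlation), with Itgam at 0.84 ± 0.08 and Clec4d at 0.72 ± 0.09. DNA replication genes fell in 30 of 33 members and 1 rose (mean -0.41, camera adjusted p = 1.07e-09, 0.306 with an estimated correlation), among them E2f1 (-0.69 ± 0.06), Dut (-0.61 ± 0.07) and Pola1 (-0.74 ± 0.10). DNA repair genes fell in 15 of 25 members (mean -0.38, camera adjusted p = 3.78e-06, 0.276 with an estimated correlation), Lig4 at -1.21 ± 0.08 and Xrcc6 at -1.14 ± 0.11. Ccnb1 was 0.08 ± 0.09 (adjusted p = 0.484).

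Resident macrophage genes rose in 14 of 17 members and 1 fell (mean 0.62, camera adjusted p = 8.48e-06, 0.193 with an estimated correlation), Marco by 1.88 ± 0.14, Hmox1 by 1.49 ± 0.09 and Spic by 1.16 ± 0.08. Mast cell, basophil and eosinophil genes rose in 12 of 15 members, 13 adjusted over the list alone (mean 0.52, camera adjusted p = 2.21e-05, 0.193 with an estimated correlation), Hdc by 0.85 ± 0.10. Interferon-stimulated genes rose in 22 of 30 members (mean 0.42, camera adjusted p = 2.28e-05, 0.39 with an estimated correlation), Rsad2 by 0.65 ± 0.10 and Oas3 by 0.56 ± 0.11. Stromal fibroblast genes rose in 11 of 14 members (mean 1.07, camera adjusted p = 5.24e-05, 0.193 with an estimated correlation), among them Mmp2 (2.67 ± 0.20), Foxc1 (1.34 ± 0.17) and Ebf3 (1.15 ± 0.15). Osteoblast genes rose in 10 of 16 members (mean 0.95, camera adjusted p = 0.000736, 0.204 with an estimated correlation), Postn by 1.46 ± 0.22 and Ibsp by 1.09 ± 0.17. The cartilage list averaged 0.96 (adjusted p = 0.445) in the same comparison.

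Niche factors rose in 9 of 12 members (mean 0.59, camera adjusted p = 0.000282, 0.193 with an estimated correlation), Igf1 by 0.96 ± 0.09 and Kitl by 0.99 ± 0.16 (0.33, adjusted p = 0.455, when its probes are averaged). Endothelial genes rose in 11 of 17 members (mean 0.51, camera adjusted p = 0.000572, 0.406 with an estimated correlation), Emcn by 1.02 ± 0.13. Immediate early and heat shock genes rose in 11 of 20 members (mean 0.41, camera adjusted p = 0.000456, 0.193 with an estimated correlation), Atf3 by 1.68 ± 0.13 and Junb by 0.47 ± 0.07. NK-cell genes rose in 9 of 13 members (mean 0.56, camera adjusted p = 0.00091, 0.311 with an estimated correlation), Klrd1 by 0.62 ± 0.10. Erythroid genes rose in 17 of 26 members and 1 fell (mean 0.28, camera adjusted p = 0.000322, 0.443 with an estimated correlation), Fech by 0.56 ± 0.10. Adipocyte genes rose in 5 of 9 members (mean 0.67, camera adjusted p = 0.00687, 0.193 with an estimated correlation), Lpl by 0.77 ± 0.07 and Pparg by 0.82 ± 0.09. Mpo (-0.03 ± 0.07, adjusted p = 0.75) and Cd3e (-0.39 ± 0.36, adjusted p = 0.391) did not pass.

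What had changed by 24 h at 8 weeks? This comparison gave 6870 genes, of which 4549 rose (66.2%), 2321 fell and 1193 moved at least 2-fold. The median difference of tested genes was 0.12, which marks no change among them. Scaled by quantiles 59.6% of called genes were higher, or 58.7% by the 75th percentile of probes well above background on all arrays. The slide-blocked count was 6766, and the shared slide gave r = 0.933. Named rises were Gdf15 (4.03 ± 0.39), Ptx3 (3.95 ± 0.31), Sfrp2 (3.71 ± 0.32), Phlda3 (3.36 ± 0.07) and the macrophage receptor Marco (3.32 ± 0.14). Bounded rises were Rspo2 (at least 4.92-fold), Ackr4 (at least 4.42-fold), Ccl12 (at least 2.54-fold), Tnfsf4 (at least 2.25-fold) and Ptgfr (at least 2.18-fold).

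Falls at 24 h included Rag1 (-4.3 ± 0.10), Smtnl2 (-3.81 ± 0.22), Bmf (-3.13 ± 0.08), Grb7 (-2.95 ± 0.59) and Rbm24 (-2.78 ± 0.53). Other probes of Bmf gave -0.78 and -1.02. Bounded falls were Sertad4 (at least 5.73-fold), Gfra1 (at least 4.35-fold), Ren1 (at least 2.83-fold), Il33 (at least 2.52-fold) and Ren2 (at least 1.72-fold). Ren1 (0.14), Ren2 (0.30), Il33 (0.16) and Mdm2 (-0.17) turn direction under normexp correction, where the background fit of 8-week 24 h replicate 3 failed. Mdm2 is 0.28 ± 0.09 (adjusted p = 0.0109) in the comparison itself. Xist, chosen after its values were seen, fell by 1.52 ± 0.15, and 1700007K13Rik, chosen in the same way, rose at least 4.45-fold.

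B-cell precursor genes fell in 16 of 16 members (mean -2.17, camera adjusted p = 5.25e-19, and 0.0462 with an estimated correlation), Vpreb3 at -2.30 ± 0.08, Lef1 at -2.71 ± 0.13 and Blnk at -1.77 ± 0.07. Mature B-cell genes fell in 13 of 17 members (mean -0.84, camera adjusted p = 1.62e-07, 0.24 with an estimated correlation), Fcrla at -2.16 ± 0.13 and Tnfrsf13c at -1.45 ± 0.12, and Cd79a fell by 1.32 ± 0.29. Of the p53 target genes 25 of 31 rose and 3 fell (mean 1.04, camera adjusted p = 4.17e-07, and 0.0462 with an estimated correlation), Aen by 1.5 ± 0.08 and Cdkn1a by 2.81 ± 0.16. Resident macrophage genes rose in 17 of 17 members (mean 1.60, camera adjusted p = 3.06e-10, 0.112 with an estimated correlation), Hmox1 by 2.16 ± 0.09 and Spic by 1.92 ± 0.08. Interferon-stimulated genes rose in 28 of 30 members (mean 1.35, camera adjusted p = 1.01e-10, 0.238 with an estimated correlation), among them Ifit3 (3.25 ± 0.19), Oasl1 (2.12 ± 0.14) and Oas1a (1.89 ± 0.14). Late neutrophil genes rose in 26 of 27 members (mean 0.69, camera adjusted p = 1.62e-07, 0.302 with an estimated correlation), Clec4e by 0.89 ± 0.08. Early granulocyte genes rose in 8 of 9 members (mean 0.64, camera adjusted p = 0.00138, 0.302 with an estimated correlation), Ctsg by 1.04 ± 0.09, Prtn3 by 0.92 ± 0.10 and Mpo by 0.61 ± 0.07.

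Stromal fibroblast genes rose in 13 of 14 members (mean 1.53, camera adjusted p = 0.000137, 0.238 with an estimated correlation), Mmp2 by 2.85 ± 0.20, Foxc1 by 2.24 ± 0.17 and Pdgfrb by 1.48 ± 0.14. Osteoblast genes rose in 11 of 16 members, 12 adjusted over the list alone (mean 1.52, camera adjusted p = 0.00125, 0.24 with an estimated correlation), Ibsp by 1.89 ± 0.17, Col1a1 by 1.77 ± 0.21 and Col1a2 by 2.0 ± 0.22. The cartilage list averaged 1.23 (adjusted p = 0.771), with 2 of 8 members past the threshold and 0 adjusted over the list alone, Sox9 at 2.49 ± 0.80 near background in the controls and 1.47 (adjusted p = 0.102) without 8-week 24 h replicate 2. Endothelial genes rose in 15 of 17 members (mean 0.97, camera adjusted p = 8.87e-05, 0.304 with an estimated correlation), including the sinusoid genes Stab1 (1.64 ± 0.14) and Stab2 (1.60 ± 0.13). Niche factors rose in 11 of 12 members (mean 1.25, camera adjusted p = 0.00025, 0.196 with an estimated correlation), Igf1 by 1.95 ± 0.09 and Bmp4 by 2.15 ± 0.14. Adipocyte genes rose in 7 of 9 members and 1 fell (mean 1.27, camera adjusted p = 0.029, 0.24 with an estimated correlation), Lpl by 2.09 ± 0.07 and Fabp4 by 1.57 ± 0.12. Megakaryocyte genes rose in 14 of 15 members, 15 adjusted over the list alone (mean 0.77, camera adjusted p = 0.00544, 0.561 with an estimated correlation), Gng11 by 1.21 ± 0.11 and Plek by 0.83 ± 0.10.

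Immediate early and heat shock genes rose in 14 of 20 members (mean 0.61, camera adjusted p = 0.0131, 0.303 with an estimated correlation), Fos by 2.89 ± 0.26 and Junb by 1.39 ± 0.07. Inflammatory cytokine genes rose in 8 of 10 members and 1 fell (mean 0.70, camera adjusted p = 0.029, 0.238 with an estimated correlation), Il18 by 1.32 ± 0.08 and Il1rn by 1.18 ± 0.12, while Il12a fell by 1.55 ± 0.10. Mitosis genes fell in 21 of 33 members (mean -0.32, camera adjusted p = 2.3e-07, 0.302 with an estimated correlation), Cenpf at -0.88 ± 0.14 and Nek2 at -0.60 ± 0.09, with Ccnb1 at -0.14 ± 0.09 (adjusted p = 0.185). DNA repair genes fell in 14 of 25 members (mean -0.31, camera adjusted p = 4.91e-05, 0.304 with an estimated correlation), Lig4 at -1.79 ± 0.08. Erythroid genes fell in 16 of 26 members and 3 rose, 17 and 3 adjusted over the list alone (mean -0.25, camera adjusted p = 8.87e-05, 0.402 with an estimated correlation), Epb42 at -0.70 ± 0.12, while Alas2 rose by 0.86 ± 0.08. DNA replication genes fell in 10 of 33 members (mean -0.14, camera adjusted p = 0.00125, 0.59 with an estimated correlation). T-cell genes had a mean of -0.06 and a median of 0.02 with 3 rising and 3 falling of 12 (adjusted p = 0.613), and Cd3e was -0.23 ± 0.36 (adjusted p = 0.603). Apoptosis machinery (adjusted p = 0.339, mean -0.11 and median 0.00), osteoclast (0.824), NF-kB target (0.383) and skeletal muscle genes (0.166) did not pass as lists, although Tnfaip3 fell by 0.76 ± 0.07 and Ctsk rose by 1.26 ± 0.25.

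**Figure D3:**
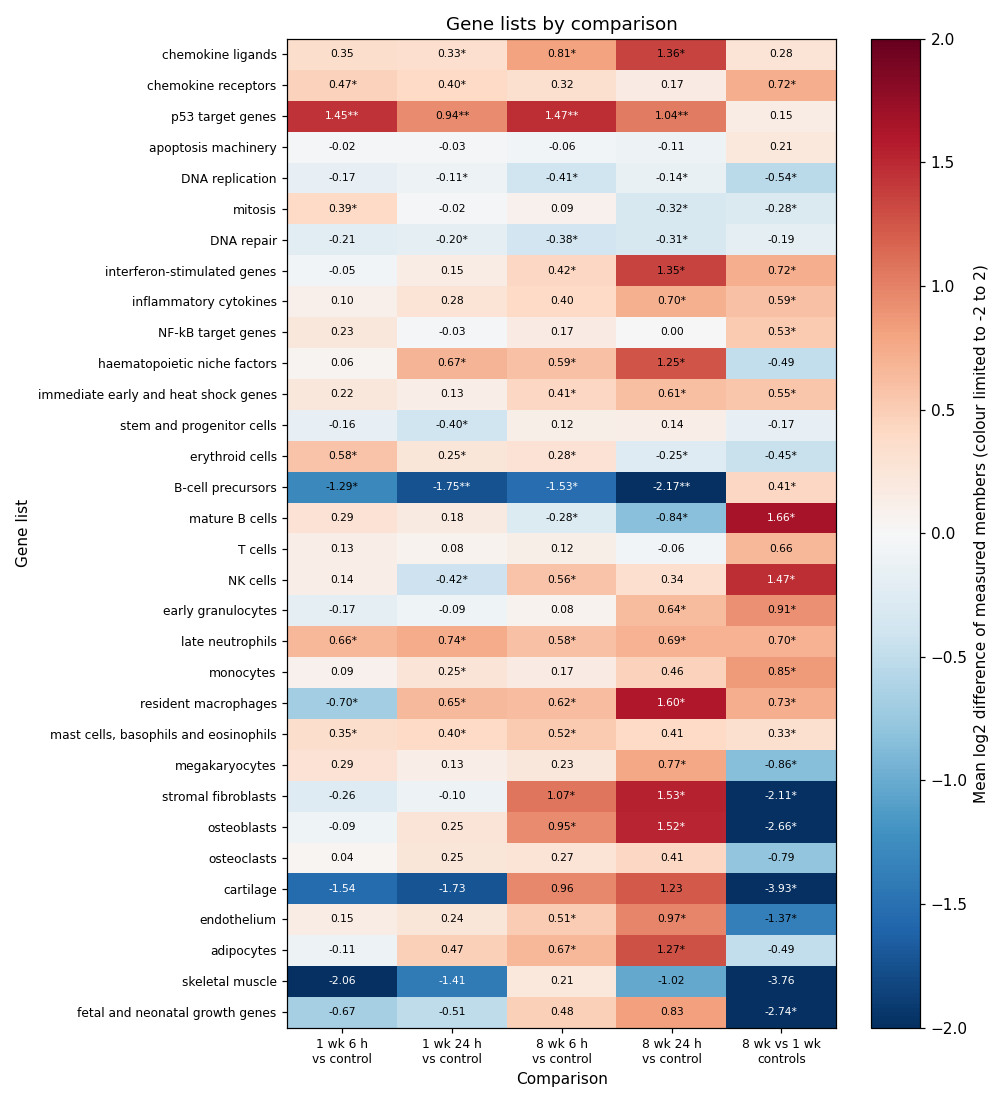
Mean log2 difference of 32 gene lists (vertical) in 5 comparisons (horizontal), 3 arrays per group, with 1 mark where camera passes adjusted p 0.05 and a double mark where the call also holds with an estimated correlation. The p53 target genes rise in all 4 irradiation comparisons (0.94 to 1.47) and B-cell precursors fall in all 4 (-2.17 to -1.29).

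How did the chemokine ligands respond? The series title names this family, so the list was chosen on these samples and its count is not independent evidence. Of 38 ligands 22 were measured, 14 were too dim and 2 have no probe named here. At 1 week 10 rose and 1 fell by 6 h (mean 0.35, camera adjusted p = 0.0592), and 8 rose and 1 fell by 24 h (mean 0.33, camera adjusted p = 0.0309, 0.373 with an estimated correlation). At 8 weeks 12 rose and 0 fell by 6 h (mean 0.81, camera adjusted p = 6.89e-05, 0.0941 with an estimated correlation). By 24 h at 8 weeks 17 rose and 0 fell, 18 and 0 adjusted over the list alone (mean 1.36, camera adjusted p = 4.91e-05, 0.0799 with an estimated correlation). With slide as a block the 4 means are 0.34, 0.27, 0.87 and 1.45, and the 1-week 24 h list no longer passes (adjusted p = 0.114). Within shared slides the list mean was 0.26 at 1 week 6 h, 0.22 and 0.37 at 1 week 24 h, 0.86 at 8 weeks 6 h and 1.46 at 8 weeks 24 h. Without 1-week control replicate 2 the 1-week 6 h list passes (0.37, adjusted p = 0.0487).

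Ccl2, a monocyte attractant, rose at both ages and times, by 2.07, 1.36, 3.0 and 3.11 (each ± 0.11) at 1 week 6 h, 1 week 24 h, 8 weeks 6 h and 8 weeks 24 h. Ccl7 rose at least 1.51-fold at 1 week 6 h, at least 1.41-fold at 8 weeks 6 h and at least 1.97-fold at 8 weeks 24 h, and Ccl12 rose at least 1.3-fold, 1.88-fold and 2.54-fold in the same groups. At 1 week 24 h Ccl12 passed (adjusted p = 0.0136) with both groups under the background limit, so no fold is given. Ccl4 rose by 0.69 ± 0.18 at 1 week 6 h and fell by 0.95 ± 0.18 at 1 week 24 h, while at 8 weeks it rose by 1.38 ± 0.18 and 1.20 ± 0.18. Ccl3 rose by 1.03 ± 0.14 and 1.17 ± 0.14 at 8 weeks, against 0.38 ± 0.14 (adjusted p = 0.0289, lost without any of several arrays) and -0.02 ± 0.14 (adjusted p = 0.917) at 1 week. Ccl25 fell by 0.26 ± 0.09 at 1 week 6 h and is 0.04 when its probes are averaged. Ccl6 rose in all 4 comparisons (0.69, 1.05, 0.41 and 0.60, each ± 0.09), as did Cx3cl1 (0.73, 0.77, 1.47 and 1.52, each ± 0.16). Ccl5 rose by 0.31 ± 0.09, 0.37 ± 0.09 and 0.68 ± 0.09 before reaching 0.19 ± 0.09 (adjusted p = 0.095) at 8 weeks 24 h.

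Cxcl12, a retention factor for stem cells, was -0.23 ± 0.16 (adjusted p = 0.227) at 1 week 6 h and then rose by 0.87 ± 0.16 at 1 week 24 h, 0.65 ± 0.16 at 8 weeks 6 h and 1.95 ± 0.16 at 8 weeks 24 h. Cxcl14 followed the same order with 0.01 ± 0.16 (adjusted p = 0.97), 1.47 ± 0.16, 1.1 ± 0.16 and 3.08 ± 0.16. Cxcl10, an interferon-induced ligand, rose by 0.74 ± 0.18, 0.75 ± 0.18 and 2.06 ± 0.18, and was 0.44 ± 0.18 (adjusted p = 0.0631) at 8 weeks 6 h. Cxcl16 rose by 0.77 ± 0.14, 0.82 ± 0.14 and 1.27 ± 0.14, and was 0.13 ± 0.14 (adjusted p = 0.514) at 1 week 24 h. At 8 weeks 24 h Cxcl9 (1.32 ± 0.36), Xcl1 (1.16 ± 0.27), Ccl8 (1.20 ± 0.34), Ccl24 (1.14 ± 0.35) and Pf4 (0.70 ± 0.26) also passed. In the test of the 24 h age difference Xcl1 passes (adjusted p = 0.00566), and Cxcl9 (0.0773), Ccl8 (0.509), Ccl24 (0.192) and Pf4 (0.0733) do not. Ccl19 rose at 8 weeks by 0.59 ± 0.20 and 0.75 ± 0.20. Pf4 is 0.52 (adjusted p = 0.1) after quantile scaling, and Ccl24 is 0.80 (adjusted p = 0.074) without 8-week 24 h replicate 3.

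**Figure D4:**
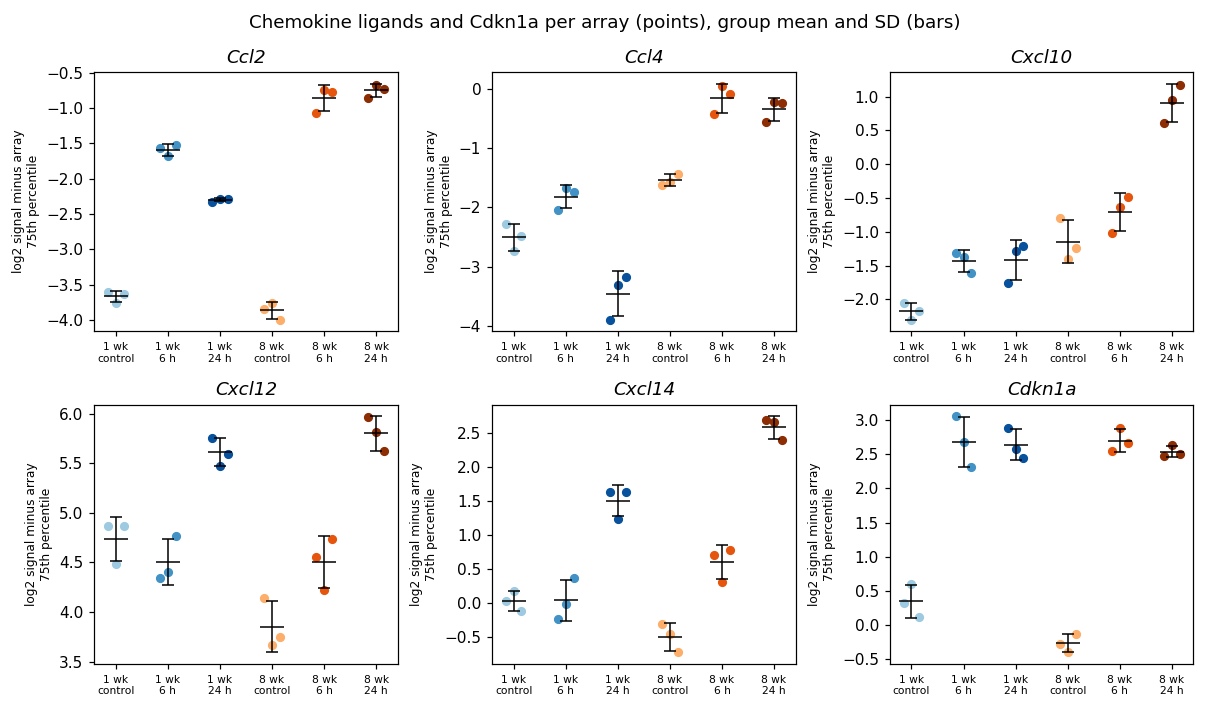
Log2 signal minus the array's 75th percentile for Ccl2, Ccl4, Cxcl10, Cxcl12, Cxcl14 and Cdkn1a in 6 groups, points are arrays (3 per group) and bars are mean and SD. Ccl2 lies at -3.66 in 1-week controls and -3.86 in 8-week controls, and reaches -1.59 and -0.86 at 6 h.

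How does unirradiated marrow differ between the ages? At 8 weeks 3258 genes were higher and 4453 lower than at 1 week, 1590 of them at least 2-fold, and 7496 differed with slide as a block. The shared slide gave r = 0.949, and 7346 genes differ without 1-week control replicate 2. Higher at 8 weeks were the immunoglobulin joining chain Jchain (6.28 ± 0.11), Klra7 (4.23 ± 0.21), Fcer1a (3.84 ± 0.13), Hspa1b (3.56 ± 0.23), Klra16 (3.41 ± 0.17) and Chst10 (3.41 ± 0.18). Bounds apply to Pla2g2d (at least 19.3-fold), Degs2 (at least 7.36-fold), Tnfrsf17 (at least 3.52-fold) and Akr1b7 (at least 3.1-fold). Lower at 8 weeks were Csta2 (-9.52 ± 0.24), Stfa3 (-6.44 ± 0.12), Stfa2 (-5.66 ± 0.12), Stfa1 (-5.45 ± 0.11) and Cstdc5 (-5.01 ± 0.13), close paralogs whose probes may not separate the copies. The growth factor Igf2 was at least 377-fold lower, Igf2bp3 at least 28-fold, Sln at least 23.8-fold and Mcpt4 at least 13.1-fold. Myh2 (-4.86 ± 1.81) is -2.92 (adjusted p = 0.155) without 1-week control replicate 2.

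Mature B-cell genes were higher in 16 of 17 members, 17 adjusted over the list alone (mean 1.66, camera adjusted p = 4.16e-09, 0.21 with an estimated correlation), Ms4a1 by 1.98 ± 0.11 and Fcmr by 2.44 ± 0.11. NK-cell genes were higher in 12 of 13 members (mean 1.47, camera adjusted p = 8.36e-07, 0.21 with an estimated correlation), Klrd1 by 2.04 ± 0.10. Early granulocyte genes were higher in 9 of 9 members (mean 0.91, camera adjusted p = 4.7e-06, 0.21 with an estimated correlation), Elane by 1.52 ± 0.13. Late neutrophil genes were higher in 24 of 27 members and lower in 2 (mean 0.70, camera adjusted p = 4.29e-10, 0.225 with an estimated correlation), Chil3 by 2.34 ± 0.08. Monocyte genes (9 higher and 2 lower of 12, mean 0.85, camera adjusted p = 0.000201, 0.225 with an estimated correlation) included Irf8 at 1.31 ± 0.08. Resident macrophage genes (13 higher and 2 lower of 17, mean 0.73, camera adjusted p = 0.000307, 0.278 with an estimated correlation) included Cd163 at 3.25 ± 0.15. Interferon-stimulated genes were higher in 22 of 30 members (mean 0.72, camera adjusted p = 8.36e-07, 0.291 with an estimated correlation), Oasl2 by 1.72 ± 0.13. Chemokine ligands were split, 9 higher and 9 lower of 22 (mean 0.28, adjusted p = 0.213), with Ccl5 at 2.54 ± 0.09 and Cxcl12 at -0.89 ± 0.16, and Ccl2 was -0.20 ± 0.11 (adjusted p = 0.112).

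Stromal fibroblast genes were lower at 8 weeks in 14 of 14 members (mean -2.11, camera adjusted p = 4.64e-06, 0.21 with an estimated correlation), Col3a1 at -3.13 ± 0.28 and Pdgfrb at -2.21 ± 0.14. Osteoblast genes were lower in 15 of 16 members and higher in 1 (mean -2.66, camera adjusted p = 1.06e-05, 0.21 with an estimated correlation), Col1a1 at -3.65 ± 0.21. Endothelial genes were lower in 16 of 17 members and higher in 1 (mean -1.37, camera adjusted p = 3.71e-06, 0.25 with an estimated correlation), Cdh5 at -2.04 ± 0.13. Fetal and neonatal growth genes were lower in 12 of 17 members and higher in 2 (mean -2.74, camera adjusted p = 0.000526, 0.21 with an estimated correlation), Mest at -3.15 ± 0.18 and Grb10 at -2.57 ± 0.14. Cartilage genes (8 lower of 8, mean -3.93, camera adjusted p = 0.04, 0.475 with an estimated correlation) and skeletal muscle genes (10 lower of 13, mean -3.76, adjusted p = 0.077) include the muscle and cartilage transcript of 1-week control replicate 2. Without that array they are -2.06 (adjusted p = 0.021) and -1.63 (adjusted p = 0.266). DNA replication genes were lower in 32 of 33 members (mean -0.54, camera adjusted p = 8.36e-07, 0.389 with an estimated correlation), Mcm3 at -0.63 ± 0.07, and mitosis genes in 18 of 33 (mean -0.28, camera adjusted p = 0.00376, 0.457 with an estimated correlation), Ccnb1 at -0.62 ± 0.09. Erythroid genes were lower in 21 of 26 members and higher in 2 (mean -0.45, camera adjusted p = 0.00126, 0.437 with an estimated correlation), Gata1 at -0.99 ± 0.08. Megakaryocyte genes were lower in 13 of 15 members and higher in 1 (mean -0.86, camera adjusted p = 0.00642, 0.457 with an estimated correlation), Gp9 at -1.31 ± 0.19.

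A further 6 lists were higher at 8 weeks, and none of the 22 calls in this comparison holds with an estimated correlation. Chemokine receptors (14 higher and 3 lower of 18, mean 0.72, camera adjusted p = 0.000201, 0.21 with an estimated correlation) included Cxcr3 at 1.17 ± 0.09. NF-kB target genes (9 higher and 1 lower of 11, mean 0.53, camera adjusted p = 0.000846, 0.225 with an estimated correlation) included Tnfaip3 at 0.92 ± 0.07. Heat shock and immediate early genes (10 higher and 1 lower of 20, mean 0.55, camera adjusted p = 0.00376, 0.25 with an estimated correlation) included Hspa1a at 3.24 ± 0.18. Inflammatory cytokine genes (7 higher of 10, mean 0.59, camera adjusted p = 0.00473, 0.21 with an estimated correlation) included Il1b at 1.72 ± 0.15. B-cell precursor genes (10 higher and 3 lower of 16, mean 0.41, camera adjusted p = 0.00473, 0.406 with an estimated correlation) included Cd72 at 2.05 ± 0.11. Mast cell, basophil and eosinophil genes (10 higher and 3 lower of 15, mean 0.33, camera adjusted p = 0.0136, 0.406 with an estimated correlation) included Prss34 at 2.34 ± 0.12. Cdkn1a was -0.62 ± 0.16, Mdm2 0.42 ± 0.09, Mpo 0.48 ± 0.07 and Cd3e 1.00 ± 0.36 (adjusted p = 0.13 with slide as a block), and Cd79a did not pass (0.39 ± 0.29, adjusted p = 0.258).

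**Figure D5:**
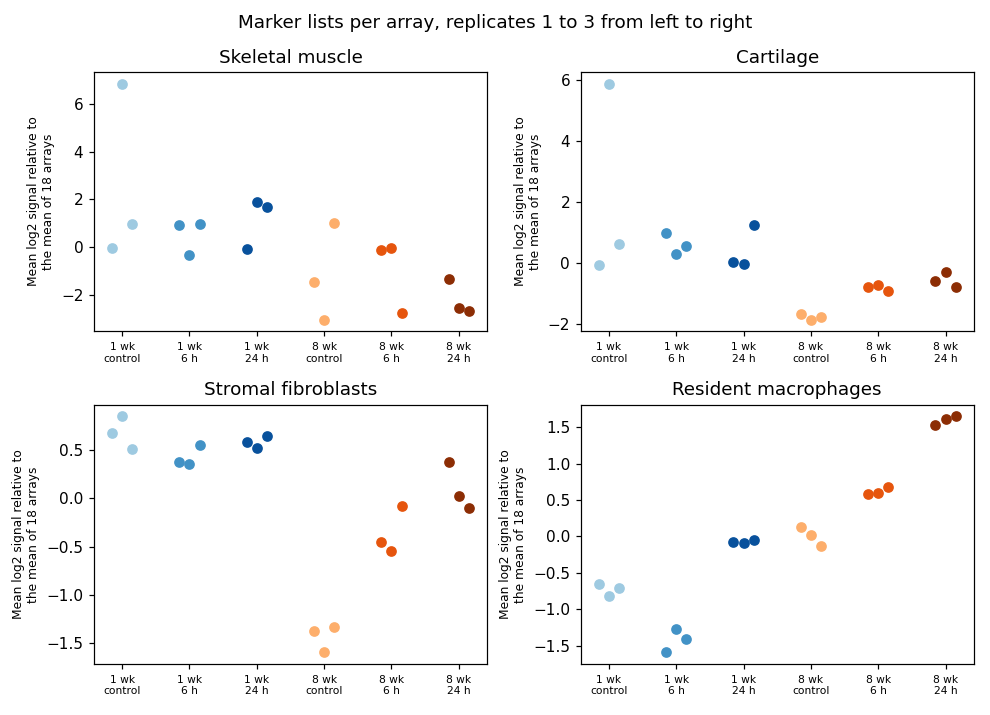
Mean log2 signal of the skeletal muscle, cartilage, stromal fibroblast and resident macrophage lists per array relative to 18 arrays, in 6 groups with replicates 1 to 3 from left to right. Stromal genes lie at 0.68 in 1-week controls and -1.43 in 8-week controls, where they reach 0.10 at 24 h.

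Where do the ages respond differently? The 6 h response differed in 2210 genes (1248 higher and 962 lower at 8 weeks, 1370 with slide as a block) and the 24 h response in 5001 (3391 higher and 1610 lower, 4565 with slide as a block). The median of all genes was 0.11 in the 24 h difference. Larger at 8 weeks by 6 h were Spats2l (3.27 ± 0.51), Tbx3 (3.41 ± 0.74), Olfr138 (3.77 ± 0.97), Anxa8 (3.89 ± 1.06), Cspg4 (4.0 ± 1.14) and Ecrg4 (5.09 ± 1.72). Lower were Aqp5 (-2.73 ± 0.74), Dnase1 (-2.54 ± 0.71), Adam33 (-2.33 ± 0.26), Fabp2 (-2.19 ± 0.66), Plcd3 (-2.16 ± 0.47) and Rph3al (-1.99 ± 0.58). With slide as a block Anxa8, Cspg4, Ecrg4, Olfr138, Aqp5, Dnase1 and Fabp2 lose the call. Without 1-week control replicate 2 Ecrg4 is 2.89 and Anxa8 2.48 by 6 h, and Ecrg4 2.49 and Nol3 2.22 by 24 h, each still past the threshold. In all of the 6 h genes except Plcd3 and Rph3al at least 1 of the 4 groups is above background on no array, so the fitted values there depend on the background and bound nothing. By 24 h the differences included Ecrg4 (4.69 ± 1.72, adjusted p = 0.2 with slide as a block), Bmper (4.14 ± 0.81, and 1.61 with adjusted p = 0.0686 when its probes are averaged), Srpx (3.66 ± 0.48), Flvcr2 (3.65 ± 0.76), Nol3 (3.62 ± 1.03) and Galnt16 (3.59 ± 0.52). Lower were Cd209b (-2.71 ± 0.50), Mageb16 (-2.66 ± 0.34), Dnase1 (-2.59 ± 0.71), Ppm1e (-2.36 ± 0.15), Adam33 (-2.35 ± 0.26) and Cd209d (-2.26 ± 0.17), of which Cd209b (0.03) and Dnase1 (0.13) turn direction under normexp correction. The same limit holds by 24 h for the 6 higher genes, Cd209b and Dnase1.

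Chemokine ligands chosen on these samples responded higher at 8 weeks in 5 of 22 members by 6 h, 7 adjusted over the list alone (mean difference 0.46, camera adjusted p = 0.0141, 0.358 with an estimated correlation), and in 12 with 1 lower by 24 h (mean 1.02, camera adjusted p = 0.0033, 0.401 with an estimated correlation). With slide as a block the shifts are 0.54 and 1.18. Ccl2 differed by 0.93 ± 0.15 and 1.75 ± 0.15, Cxcl12 by 0.88 ± 0.22 (adjusted p = 0.0804 with slide as a block) and 1.07 ± 0.22, Cxcl14 by 1.09 ± 0.23 and 1.60 ± 0.23, and by 24 h Ccl4 by 2.15 ± 0.25. Cxcl12 was at 4.505 and 4.504 by 6 h and 5.61 and 5.80 by 24 h at 1 and 8 weeks. Most of its difference lies in the controls (4.74 and 3.85). Ccl7 and Ccl12 also passed by 24 h, with both 1-week groups and the 8-week control under the background limit, so their fitted sizes carry no meaning beyond the call. The list mean of 1.02 includes them. Stromal fibroblast genes differed in 8 and 12 of 14 members (means 1.33 and 1.63, camera adjusted p = 9.27e-08 and 1.12e-05, 0.178 and 0.401 with an estimated correlation). Resident macrophage genes differed in 15 of 17 members at each time (means 1.32 and 0.94, camera adjusted p = 1.11e-16 and 7.23e-06, 0.0872 and 0.401 with an estimated correlation). Interferon-stimulated genes differed in 10 and 27 of 30 members (means 0.46 and 1.20, camera adjusted p = 5.56e-05 and 4.08e-10, 0.51 and 0.401 with an estimated correlation). Mature B-cell genes responded lower at 8 weeks than at 1 week in 6 and 12 of 17 members (mean differences -0.57 and -1.02, camera adjusted p = 9.23e-05 and 4.08e-10, 0.502 and 0.401 with an estimated correlation), and at 1 week the list itself was 0.29 by 6 h (adjusted p = 0.417) and 0.18 by 24 h (adjusted p = 0.207). Xist differed at -0.78 ± 0.22 and -1.53 ± 0.22. Members of the p53 target list went both ways, 3 higher and 4 lower of 31 by 6 h (Phlda3 at 0.64 ± 0.10, Trp53inp1 at -0.74 ± 0.12) and 8 higher and 6 lower by 24 h (Gdf15 at 2.93 ± 0.54, Phlda3 at 0.75 ± 0.10, Trp53inp1 at -0.65 ± 0.12, Sesn1 at -0.50 ± 0.09). The list mean was 0.02 by 6 h (median -0.06, adjusted p = 0.362) and 0.10 by 24 h (adjusted p = 0.409), with camera's direction down at both times. Cdkn1a did not pass (0.64 ± 0.23, adjusted p = 0.064, and 0.52 ± 0.23, adjusted p = 0.081). Late neutrophil members also went both ways, 1 higher and 2 lower of 27 by 6 h (Stfa1 at 0.64, adjusted p = 0.0509 with slide as a block, Chil3 at -0.62 ± 0.11) and 4 higher and 3 lower by 24 h (Stfa1 at 1.26, Ngp at -0.41 ± 0.10), around means of -0.08 (adjusted p = 0.2) and -0.05 (adjusted p = 0.0719).

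How do the responses at the ages compare gene by gene? Across 11884 genes, which are not independent, the 6 h differences correlate at r = 0.521 (rho 0.556) and the 24 h differences at r = 0.41 (rho 0.32, and r = 0.223 without a background filter). At 6 h 1642 genes rose at both ages where 725.1 would by independence, 1794 fell at both (691.6 by independence) and 225 went opposite ways (1418). At 24 h the counts were 1402 (839.1), 765 (407.6) and 683 (1227).

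How does 24 h differ from 6 h? At 1 week 2205 genes were higher and 2094 lower at 24 h, and at 8 weeks 3916 were higher and 1956 lower. Slide-blocked counts were 3974 and 5958 genes, and within slides r was 0.863 at 1 week and 0.893 and 0.926 at 8 weeks. At 1 week Ica1l (2.71 ± 0.29), Gbp8 (2.59 ± 0.12) and Fcna (2.28 ± 0.11) were higher, with bounds for Ido2 (at least 2.68-fold), Sfrp2 (at least 2.27-fold) and Trabd2b (at least 1.48-fold). Ddx25 (-4.12 ± 0.50), Tgm5 (-4.09 ± 0.43), Pdpk1 (-4.0 ± 0.43), Trim55 (-3.90 ± 0.43) and Myo1e (-3.77 ± 0.49) returned to a lower signal, and Aqp5 was at least 11.2-fold lower. At 8 weeks Ifit3 (2.77 ± 0.19), Fos (2.74 ± 0.26), Rbp4 (2.68 ± 0.31) and Sfrp2 (2.60 ± 0.32) were higher, with Gng13 at least 2.16-fold and Ptgfr at least 1.52-fold. Ddx25 (-3.73 ± 0.50), Trim55 (-3.73 ± 0.43), Pdpk1 (-3.51 ± 0.43), Myo1e (-3.29 ± 0.49) and Tgm5 (-2.64 ± 0.43) were lower, as was Cys1 (at least 2.02-fold, and 0.25 under normexp correction). Other measured probes of Pdpk1 and Myo1e lay between -0.57 and -0.02 in these comparisons, and a dimmer probe of Myo1e at -0.50 and -1.06.

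The p53 target genes were lower at 24 h than at 6 h in 23 of 31 members and higher in 2 at 1 week (mean -0.51, camera adjusted p = 5.95e-10, and 0.0125 with an estimated correlation), and in 22 and 3 at 8 weeks (mean -0.43, camera adjusted p = 8.88e-10, and 0.0135 with an estimated correlation). Bbc3 lay at -1.14 ± 0.08 and -0.93 ± 0.08 and Mdm2 at -0.33 ± 0.09 and -0.56 ± 0.09, while Cdkn1a was -0.04 ± 0.16 and -0.16 ± 0.16. Resident macrophage genes were higher in 16 of 17 members at 1 week, 17 adjusted over the list alone (mean 1.35, camera adjusted p = 1.62e-16, and 0.0451 with an estimated correlation), and in 17 at 8 weeks (mean 0.98, camera adjusted p = 3.35e-08, 0.363 with an estimated correlation). Timd4 rose by 1.91 ± 0.10 at 1 week and Siglec1 by 2.17 ± 0.19 at 8 weeks. Mitosis genes were lower in 29 of 33 and 25 of 33 members (means -0.41 at each age, camera adjusted p = 3.09e-11 and 2.94e-10, 0.456 and 0.423 with an estimated correlation), Ube2c at -0.82 ± 0.09 and -1.09 ± 0.09. Chemokine ligands had 4 higher and 5 lower at 1 week (mean -0.02, adjusted p = 0.769) and 9 higher and 1 lower at 8 weeks (mean 0.55, adjusted p = 0.183).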

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

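All tests in this part were chosen only after the result was seen, apart from the slide tests, the counts over other splits of the arrays and the tests of differences between groups. Groups hold 3 arrays, so no test for a single deviating array was run.

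The used probes of Pdpk1, Ddx25, Trim55, Lifr, Tgm5, Myo1e and Plcd3 rose together 6 h after irradiation at 1 week (mean 3.76) and at 8 weeks (2.25). Slide is argued against as the whole cause, since the mean with slide as a block is 3.88 ± 0.35. A candidate explanation is that these probes measure a transcript that other probes of the genes do not, as the median of the 5 other probes (of Pdpk1, Lifr and Myo1e only) is 0.16, and which transcript it would be was not tested. Adhering skeletal muscle is argued against as the whole cause of the rise, since that list was at -2.06 ± 1.59 in the same comparison. Without 1-week control replicate 2 the list was at 0.07 ± 1.17. In that muscle-rich array the 7 genes lie only 0.44 above the other controls. A smaller part from muscle stays open. A biological cause stays open too, with the ages differing in Plcd3 (-2.16 ± 0.47) and not past the threshold in the other 6 genes (adjusted p from 0.0587 for Tgm5 to 0.336 for Myo1e).

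Muscle and cartilage lists stand 6.39 and 5.60 above the other 1-week controls in replicate 2, against 0.43 for osteoblasts, 0.25 for stromal fibroblasts, -0.02 for T cells and 0.06 for late neutrophils. All 21 of 21 measured members of both lists are higher in it than in both other controls, which may come from muscle and cartilage adhering at dissection. A fault shared by its whole slide is argued against as the source of the 6.39 shift. The other arrays of that slide differ from their group mates in the muscle list by -0.34 ± 0.95 (-1.87, 1.41 and -0.55). A smaller slide effect stays open. No biological explanation was tested, because the arrays share a group.

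Stromal fibroblast genes rose by 1.53 at 8 weeks 24 h, a list call that is lost with an estimated correlation (adjusted p = 0.238). Loss of B-lineage cells alone would lift other cell types alike, and the stromal list exceeds the T-cell list by 1.59 ± 0.19. T cells are radiosensitive as well, so this comparison cannot tell whether a wider loss of sensitive cells lifts the stromal list. Blocked by slide the rise is 1.51 ± 0.19, so slide is argued against as its whole cause. Adhering bone and cartilage could add to it, since the cartilage list is at 1.23 ± 1.12, too wide to decide. A change in stromal cells or in their yield stays open, untested.

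Other splits of the compared arrays (10 per comparison, which are too few for a share under 0.05) gave a result as large in 1 of 10, the real split, in each case. Real and highest other counts were 6161 and 0 (1 week 6 h), 4279 and 1 (1 week 24 h), 5469 and 1 (8 weeks 6 h), 6870 and 0 (8 weeks 24 h), 7711 and 0 (age in controls), 2210 and 0 (6 h age difference), 5001 and 0 (24 h age difference), 4299 and 1 (24 h against 6 h at 1 week) and 5872 and 0 (at 8 weeks). For the age differences responses relative to controls were exchanged. For the chemokine ligand mean the pairs were 0.35 and 0.20, 0.33 and 0.19, 0.81 and 0.41, 1.36 and 0.55, 0.46 and 0.36, and 1.02 and 0.44 in the 4 irradiation comparisons and the 2 age differences.

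The response to irradiation differed between ages, tested as a difference of differences, in 2210 genes at 6 h. Lists higher at 8 weeks were chemokine ligands (0.46), interferon (0.46), niche (0.53), NK cells (0.43), early granulocytes (0.25), resident macrophages (1.32), stromal fibroblasts (1.33), osteoblasts (1.03), endothelium (0.37), adipocytes (0.77) and fetal growth (1.15). Lower were DNA replication (-0.24), mitosis (-0.30), DNA repair (-0.17), erythroid (-0.29) and mature B (-0.57). None of these 16 list calls holds with an estimated correlation (adjusted p = 0.0872 to 0.582). Among genes, Ecrg4 (5.09), Cspg4 (4.0), Anxa8 (3.89), Olfr138 (3.77), Tbx3 (3.41), Spats2l (3.27), Cxcl14 (1.09), Ccl2 (0.93), Cxcl12 (0.88), Cx3cl1 (0.73), Ccl3 (0.65) and Mpo (0.30) were higher. Aqp5 (-2.73), Dnase1 (-2.54), Adam33 (-2.33), Fabp2 (-2.19), Plcd3 (-2.16) and Rph3al (-1.99) were lower. For Ecrg4, Cspg4, Anxa8, Olfr138, Tbx3, Spats2l, Aqp5, Dnase1, Adam33 and Fabp2 at least 1 of the 4 groups is above background on no array, so these are fitted values that depend on the background and are no bounds.

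By 24 h 5001 genes differed between ages. Higher lists were chemokine ligands (1.02), interferon (1.20), NK cells (0.75), early granulocytes (0.73), resident macrophages (0.94), stromal fibroblasts (1.63), osteoblasts (1.26), endothelium (0.73) and fetal growth (1.34), and lower ones chemokine receptors (-0.23), mitosis (-0.31), DNA repair (-0.11), erythroid (-0.50), B-cell precursors (-0.42) and mature B (-1.02). With an estimated correlation 0 of these 15 calls hold (adjusted p = 0.401 to 0.694). Higher genes were Ecrg4 (4.69), Bmper (4.14), Srpx (3.66), Flvcr2 (3.65), Nol3 (3.62), Galnt16 (3.59), Ccl7 (2.73), Ccl12 (2.31), Ccl4 (2.15), Ccl2 (1.75), Cxcl14 (1.60), Xcl1 (1.45), Cxcl10 (1.31), Ccl3 (1.20), Cxcl16 (1.14), Cxcl12 (1.07), Mpo (0.96), Ccl19 (0.80) and Cx3cl1 (0.75). Lower genes were Cd209b (-2.71), Mageb16 (-2.66), Dnase1 (-2.59), Ppm1e (-2.36), Adam33 (-2.35), Cd209d (-2.26), Ccl6 (-0.45) and Mdm2 (-0.36). Fitted values without a bound, for the same reason, are those of Ecrg4, Bmper, Srpx, Flvcr2, Nol3, Galnt16, Ccl7, Ccl12, Xcl1, Cd209b and Dnase1, of which the sizes of Ccl7 and Ccl12 carry no meaning beyond the call.

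Effects of irradiation differed between 24 h and 6 h at 1 week in 4299 genes. Lists higher at 24 h were niche (0.62) and resident macrophages (1.35), and lower were p53 targets (-0.51), mitosis (-0.41), NF-kB targets (-0.26), stem cells (-0.24), erythroid (-0.33), B-cell precursors (-0.46) and NK cells (-0.55). With an estimated correlation p53 targets (adjusted p = 0.0125) and resident macrophages (0.0451) hold, and the other 7 calls do not (0.456 to 0.537). Genes were Trabd2b (2.81), Ica1l (2.71), Sfrp2 (2.66), Ido2 (2.64), Gbp8 (2.59), Fcna (2.28), Aqp5 (-4.33), Ddx25 (-4.12), Tgm5 (-4.09), Pdpk1 (-4.0), Trim55 (-3.90) and Myo1e (-3.77). Against a group not above background bounds are given, at least 1.48-fold for Trabd2b, 2.27-fold for Sfrp2, 2.68-fold for Ido2 and 11.2-fold for Aqp5. Their log2 values are fitted. At 8 weeks 5872 genes differed, with DNA replication (0.26), interferon (0.93), niche (0.67), early granulocytes (0.56), resident macrophages (0.98) and endothelium (0.46) higher at 24 h. Chemokine receptors (-0.15), p53 targets (-0.43), mitosis (-0.41), NF-kB targets (-0.17), erythroid (-0.53), B-cell precursors (-0.64) and mature B (-0.56) were lower. Of these 13 calls p53 targets (0.0135) holds with an estimated correlation, and the other 12 do not (0.363 to 0.717). Genes were Ifit3 (2.77), Fos (2.74), Ptgfr (2.74), Rbp4 (2.68), Gng13 (2.65), Sfrp2 (2.60), Ddx25 (-3.73), Trim55 (-3.73), Pdpk1 (-3.51), Myo1e (-3.29), Cys1 (-2.72) and Tgm5 (-2.64). Those of Ptgfr, Gng13 and Cys1 are fitted too, with bounds of at least 1.52-fold, 2.16-fold and 2.02-fold, and Cys1 is 0.25 under normexp.

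Probes without a gene symbol also moved after irradiation. Of 5914 tested transcripts, 2270 changed at 1 week 6 h (1512 higher and 758 lower), 1385 at 1 week 24 h (790 and 595), 1509 at 8 weeks 6 h (730 and 779) and 3460 at 8 weeks 24 h (1011 and 2449).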

How the results depend on the processing

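The version of normexp with bright backgrounds reset was the only test here chosen after the result was seen. Counts are given in the order 1 week 6 h, 1 week 24 h, 8 weeks 6 h, 8 weeks 24 h, age in controls, 6 h age difference, 24 h age difference, 24 h against 6 h at 1 week and at 8 weeks. Planned normexp gave 1286, 672, 758, 3505, 2810, 134, 978, 419 and 1854 genes, 13 lists at 1 week 6 h, and chemokine ligands at 0.29 (adjusted p = 0.0389) at 1 week 6 h and 0.22 (0.0615) in the 6 h age difference. Its fit broke on 8-week 24 h replicate 3, where 11 spots carry a background above 10 times the array median and the fitted mean is -989.6 against 1.9 to 12.5 on the other arrays. With these backgrounds reset the fitted mean is 6 and the counts are 6037, 3659, 5225, 6437, 7182, 1803, 4172, 3416 and 4923, with chemokine ligands at 0.29 (0.0158) at 1 week 6 h. Under planned normexp 7 of the named genes and 2 lists turned direction. These are Ren1 (0.14), Ren2 (0.30), Il33 (0.16) and Mdm2 (-0.17) at 8 weeks 24 h, Cd209b (0.034) and Dnase1 (0.13) in the 24 h age difference, and Cys1 (0.25), DNA replication (-0.10) and late neutrophils (-0.33) for 24 h against 6 h at 8 weeks. None of them turned with the backgrounds reset. Ccl25 at 1 week 6 h turned to 0.036 with the mean of its probes. Apart from the normexp cases, the cause of a changed result was not tested.

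Chemokine ligands at 1 week 6 h, not past the threshold as reported, passed with the mean of probes (0.40, 0.0487) and with fry (0.35, 3.6e-05), which does not compare with other genes. Ranges of its adjusted p here are over camera alternatives, without fry, and at 1 week 6 h this is 0.0158 to 0.597. At 1 week 24 h the list missed the threshold without a background filter (0.21, 0.0717), with slide as a block (0.27, 0.114), with array weights (0.32, 0.0546) and with an estimated correlation (0.33, 0.372), over a range of 0.00348 to 0.372. The 6 h age difference missed it for genes well above background on all arrays (0.33, 0.0507) and with an estimated correlation (0.46, 0.358), over a range of 0.00502 to 0.358. With an estimated correlation it also missed in the 24 h age difference (1.02, 0.401, range 0.000873 to 0.401), at 8 weeks 6 h (0.81, 0.0941, range 1.87e-05 to 0.0941) and at 8 weeks 24 h (1.36, 0.0799, range 3.96e-06 to 0.0799). The lists past the threshold then numbered 1, 2, 1, 2, 0, 0, 0, 2 and 1, and fry gave 14 at 1 week 6 h and 20 for 24 h against 6 h at 8 weeks. Slide as a block left 1370 genes in the 6 h age difference. At adjusted p under 0.01 the counts moved to 2829 (1 week 24 h), 883 and 3176 (age differences) and 2783 (24 h against 6 h at 1 week), and with a 2-fold minimum to 392, 390, 474, 1193, 1590, 352, 910, 226 and 441. Without a background filter the 24 h agreement between ages was r = 0.223.

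Leaving out each array in turn gave 5299 to 6108, 3320 to 4066, 4491 to 5206, 6142 to 6362, 7187 to 7390, 1577 to 2106, 4308 to 4844, 3380 to 3953 and 4950 to 5658 genes. Chemokine ligands ran from 0.26 to 0.40 at 1 week 6 h, passing without 1-week control replicate 2 (0.37, 0.0487) and without 6 h replicate 1 (0.40, 0.039) or replicate 3 (0.40, 0.0493). At 1 week 24 h they ran from 0.29 to 0.38, missing the threshold without 24 h replicate 3 (0.29, 0.086), and the lists past the threshold there ran from 9 (without that array) to 19. Agreement between ages ran from 0.446 to 0.603 at 6 h and from 0.338 to 0.466 at 24 h.

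Genes that lose their call without a single array include these, with the replicates concerned and the range of values. At 1 week 6 h they are Ccl3 (control 1 and 3, 6 h 1 and 2, 0.29 to 0.36), Ccnb1 (control 1 and 2, 6 h 1, 2 and 3, 0.22 to 0.25), Myom2 (control 2, 6 h 2, -2.58 to -1.65), Apobec2 (control 2, 6 h 2, -2.78 to -1.25) and Ccl25 (control 2 and 3, 6 h 2, -0.23 to -0.20), and at 1 week 24 h Myom2 (control 2, 24 h 1, 2 and 3, -3.03 to -1.17) and Ccl12 (control 3, 24 h 1). At 8 weeks they are Ccl19 at 6 h (control 2 and 3, 6 h 2 and 3, 0.52 to 0.56) and at 24 h Pf4 (control 2 and 3, 24 h 2, 0.56 to 0.67), Ccl24 (control 3, 24 h 3, 0.80 to 0.93), Sox9 (24 h 2, 1.47) and Mdm2 (24 h 3, 0.21). Between control groups they are Cd3e (1-week 1 and 3, 8-week 3, 0.42 to 0.96) and Myh2 (1-week 2, 8-week 2, -3.39 to -2.92), and for 24 h against 6 h at 1 week Ido2 (6 h 3, 24 h 1 and 2, 2.04 to 2.35).

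In the 6 h age difference the call of Mpo (0.25 to 0.31) is lost without any of 9 arrays (all but 1-week control 2, 1-week 6 h 3 and 8-week 6 h 2) and that of Ecrg4 (4.69 to 5.67) without any of 8 (all but the 1-week controls and 1-week 6 h 1). Cx3cl1 (0.55 to 0.76) loses it without 1-week control 1, 1-week 6 h 1 or 2, 8-week control 2 or 3 or 8-week 6 h 3, Fabp2 (-2.08 to -1.88) without 1-week control 2 or 3, 1-week 6 h 3, 8-week control 3 or 8-week 6 h 2 or 3, and Ccl3 (0.52 to 0.63) without 1-week control 2, 1-week 6 h 3, 8-week control 1 or 3 or 8-week 6 h 2 or 3. The same holds for Rph3al (1-week 6 h 1 and 2, 8-week control 2, 8-week 6 h 3, -1.91 to -1.55), Dnase1 (1-week 6 h 3, 8-week control 1, 8-week 6 h 1, -2.45 to -2.06), Xist (1-week control 2, 1-week 6 h 1, 8-week control 1, -0.74 to -0.65) and Cspg4 (8-week control 1, 3.76). In the 24 h age difference Ecrg4 (4.36 to 4.85) depends on 8 arrays (all but the 1-week controls and 8-week control 1), Ccl19 (0.64 to 0.78) on 1-week control 1, 1-week 24 h 1 and 2, 8-week control 2 and 3 and 8-week 24 h 1, and Mdm2 (-0.34 to -0.26) on 1-week control 1, 1-week 24 h 2 and 3, 8-week control 3 and 8-week 24 h 2.

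Under a slide block Rgma, Ccl25, Ccl5, Apobec2, Myom2 (24 h), Ccl19 (8 weeks 6 h), Myh2, Cd3e, Trabd2b and Ido2 also lose the call, and in the age differences Ccl3, Cx3cl1, Cxcl12, Mpo and Mdm2 besides Anxa8, Cspg4, Ecrg4, Olfr138, Aqp5, Dnase1 and Fabp2. Lists that miss the threshold without a single array are chemokine receptors at 1 week 6 h (6 h 2, 0.39), DNA replication (-0.06 and -0.05), DNA repair (-0.14 and -0.15) and chemokine receptors (0.36 and 0.32) at 1 week 24 h without control 3 or 24 h 3, monocytes there (control 2 and 3, 24 h 3, 0.22 to 0.24), mature B cells at 8 weeks 6 h (control 3, 6 h 3, -0.25 and -0.14), adipocytes at 8 weeks 24 h (24 h 1, 1.09) and cartilage between controls (8-week 2, -3.89), besides further lists in the age differences and between times. Calls kept at another size without 1 array are fetal growth (0.76, 1-week control 2) and erythroid (-0.17, 8-week 6 h 1) in the 6 h age difference, DNA repair (-0.17, 1-week control 3) and chemokine receptors (-0.14, 1-week 24 h 3) in that at 24 h, and Pf4 between times at 8 weeks (1.11, 6 h 3). Over all alternatives the named genes kept direction and call in 10561 cases, lost the call in 437, gained it in 75 and turned direction in 8, and the lists did so in 6133, 216, 216 and 2 cases. Scan date was not run as a block, since all arrays were scanned on 1 day. Folds of genes near background in the lower group depend on the background correction. The at least N-fold values share this and ignore spread.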

Other observations

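Both tests that this part leans on, the stromal list against the T-cell list and the median of other probes, were chosen only after the result was seen.

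At 1 week the resident macrophage list was lower 6 h after irradiation (-0.70) and higher at 24 h (0.65), while at 8 weeks it was higher at both times (0.62 and 1.60). None of these 4 list calls holds with an estimated correlation (adjusted p = 0.597, 0.167, 0.193 and 0.112). At 8 weeks the stromal list also rose, from a lower level in controls than at 1 week, and its call is lost with an estimated correlation (adjusted p = 0.193 at 6 h and 0.238 at 24 h). A candidate explanation is that loss of radiosensitive cells enriches resistant ones. The stromal list exceeds the T-cell list by 1.59, which does not argue against it, since T cells are radiosensitive as well. Counts of macrophages, stromal and B-lineage cells per femur at each time would test how much of these shifts is composition.

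The chemokine rise at 8 weeks 24 h holds Ccl2, Ccl7 and Ccl12, adjacent monocyte attractants, together with the interferon-induced Cxcl9 and Cxcl10. The interferon list rises in the same group (1.35) and less at 6 h (0.42), both not past the threshold with an estimated correlation (adjusted p = 0.238 and 0.39). These may share a source in macrophages clearing dead cells, a hypothesis the data do not test, and with an estimated correlation the chemokine list does not pass there (adjusted p = 0.0799, range over camera alternatives 3.96e-06 to 0.0799). Sorted macrophages, or irradiation with the interferon receptor blocked, would test it.

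Xist fell by 1.52 at 8 weeks 24 h and the 24 h response differed between ages (-1.53), although all mice are female per the labels. A lower share of lymphocytes could lower it, as the mature B-cell list was lower at 8 weeks (-0.28 and -0.84 at 6 h and 24 h, lost with an estimated correlation, adjusted p = 0.675 and 0.24), while at 1 week it did not pass (adjusted p = 0.417 and 0.207). Against it, at 1 week 24 h B-cell precursor genes averaged -1.75 while Xist was 0.01 (adjusted p = 0.968), and at 6 h -1.29 while Xist was 0.42 (adjusted p = 0.0316, and 0.0594 to 0.146 without control replicate 2 or 3 or 6 h replicate 1 or 3). Between controls the mature B list was 1.66 higher at 8 weeks while Xist was 0.32 (adjusted p = 0.0787). Also open is another transcript at its probe, as may hold for the probes that rose with Pdpk1, where other probes of the same genes had a median of 0.16. PCR across an Xist exon junction in sorted cells would separate these hypotheses.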
